A study of Mus musculus with 22 samples.

How the data were processed

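RNAPII was measured by ChIP-seq with an antibody against RBP1 (Active Motif) in E14tg2a mouse embryonic stem cells with cRAF-ErT2. Per the labels, 11 immunoprecipitated libraries (0h, 2h and 8h of 4OHT from clones a, b and c, and 8h with MEK inhibitor from clones b and c) and 11 inputs were made with NEB Next Ultra 2. The submitters' processing notes name Bowtie2, bedtools and mm10. Per the deposited tables, the authors give a signal value for each of 2 regions of 3708 genes, named 5′ and 3′, with 1 pooled column for each of 0h, 2h, 8h, 8h with MEK inhibitor and Input. The deposited log2 columns were made by the authors as log2 ratios of 2 such columns, and they equal the ratios computed here, apart from rounding, for every pair that could be compared. A further sheet repeating these log2 columns was not used here. Which libraries entered each pooled column, how the columns were scaled and how the genes were chosen is not stated.

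Signal values turned out to be whole multiples of a fixed step in each column, so the reads behind each value could be recovered. All of the values lay within 0.1 reads of a whole number in the immunoprecipitated columns, where chance gives 20%. The reads over the regions named 3′ and 5′ were 1749695 and 2008362 at 0h, 2296488 and 2484907 at 2h, 3018084 and 3072886 at 8h, 2546944 and 2705922 with MEK inhibitor, and 3181897 and 2971316 in Input. These are sums over the listed regions, not library depths, and some regions overlap. The median half-width of the counting interval of a log2 ratio was between 0.18 and 0.22 over the comparisons and ends.

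The design, written before the data were examined, assumed values per library and a test with replicates. With pooled columns no own test could be made, so genes were counted past a log2 ratio of at least 1 in size, with 0.5 as an alternative. For each of 5 comparisons (2h and 8h over 0h, 8h over 2h, and MEK inhibitor over 8h and over 0h) and each end, the log2 ratio of the deposited signals was computed with no pseudocount and no filter. The relative log2 ratio is this value minus its median over all genes. Counting intervals (95%) treat the reads of the 2 columns as Poisson counts. Genes at 0 in either column have no ratio. The low-value filter of the design (lower 25% of mean signal left out) was given as an alternative instead, since the deposited ratios use all genes.

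Gene lists were fixed before the data were examined. With measured and listed members they are ERK immediate response (21 of 27), ERK feedback and ETS targets (18 of 24), naive pluripotency (18 of 24), general pluripotency (13 of 14) and primitive endoderm (7 of 33). The others are formative and primed epiblast (12 of 18), other germ layers and trophoblast (8 of 17), fibroblasts (1 of 12), WNT targets (4 of 12), MYC and ribosome biogenesis (16 of 20), housekeeping (14 of 18) and replication histones (9 of 11). For each list with at least 3 members the median relative log2 ratio was placed among the medians of 10000 random lists of the same size, matched on 10 bins of mean signal over the 4 conditions. The percentile describes these libraries and carries no replicate error. Lists were called outside the middle 95% of random lists. The difference between ends (relative log2 named 5′ minus named 3′) was handled in the same way.

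Genes named in the text follow a rule fixed beforehand. Per comparison and end these are up to 4 members of each list with the largest log2 ratios, and for the ERK, naive and primitive endoderm lists also the 2 members with the highest mean signal. Added are the 6 highest and 6 lowest ratios among genes with mean signal above the median. The rule also names in every comparison, where measured, Egr1, Fos, Dusp6, Spry4, Etv4, Nanog, Klf4, Esrrb, Pou5f1, Gata6, Sox17, Otx2 and Myc. Of these, Esrrb and Gata6 are not in the tables, and Etv4 was measured but its values are not given in the text. Not every gene picked by the rule is given a value in each comparison. The part of the rule asking for the same direction in every clone could not be applied.

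Overlap between 2h and 8h and the correlations between comparisons were set beside 100 simulated draws of Poisson counts without any difference, keeping the shared columns. The length of the regions was checked from their own coordinates. RefSeq gene positions were looked up by symbol or synonym and drawn for Nanog and Klf4, and strands of 18 well-known genes were written down by hand. Alternatives fixed before the data were examined were median-centring, quantile normalization, filters on mean signal (lower 25% or 50% left out) and the limit of 0.5. Chosen after seeing the data were pseudocounts of 1 and 4, subtraction of Input (at least 5 units left in both conditions), leaving out regions overlapping another by at least 80%, and leaving out the genes at 0 at 2h. The procedure was tested on simulated data with 3708 genes, 200 of them changed. Counting intervals covered the true value in 95.1%, the limit was passed by 100% of genes changed 4-fold, 55.2% changed 2-fold (the limit itself), 1.49% changed 1.5-fold and 0.057% of unchanged genes, and 3.50% of 200 unchanged lists fell outside the middle 95%. Bootstrap intervals used 1000 draws with seed 523. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.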

Results

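RNA polymerase II (RNAPII) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against RBP1, its large subunit, in E14tg2a mouse embryonic stem cells. The cells carried cRAF-ErT2, a RAF kinase fused to a hormone-binding domain that 4-hydroxytamoxifen (4OHT) switches on, so that adding 4OHT activates MEK and ERK. Per the labels, cells were grown with serum, LIF and 2 uM CHIR99021, a GSK3 inhibitor that activates WNT signalling. For 24 h before treatment they had medium with serum, LIF and 250 nM PD173074, an inhibitor of FGF receptors. They were then left untreated (0h) or given 250 nM 4OHT for 2 h (2h) or 8 h (8h), and a further group had 8 h of 4OHT and then 2 h of the MEK inhibitor PD0325901 (8h with MEK inhibitor). The 22 libraries comprise 11 immunoprecipitated and 11 input samples, from 3 clones (a, b and c) at each of 0h, 2h and 8h and from clones b and c with MEK inhibitor. The tables hold 3708 genes, each with 1 pooled value per condition for each end of the gene. No value for a single clone is given, so no difference has a replicate error or a test, and sizes are reported instead.

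The reads behind the 2 regions of all genes, recovered from the values, came to 3758057 at 0h, 4781395 at 2h, 6090970 at 8h, 5252866 with MEK inhibitor and 6153213 for the pooled Input. The total depth of each library is not given. In this report, intervals in square brackets or after a signal are 95% counting intervals for these reads. They cover counting error only, not differences between clones or PCR copies. RNAPII signal stood above Input over most genes. In the regions named 5′ the median ratio to Input was 2.503 at 0h, 2.23 at 2h, 2.86 at 8h and 3.38 with MEK inhibitor. In regions named 3′, it was 2.13, 2.11, 2.90 and 3.10 in the same order. At or below Input were 3.02%, 2.99%, 3.13% and 1.62% of the regions named 5′ and 1.48%, 2.00%, 1.32% and 0.701% of those named 3′.

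The signal of the median gene differed between conditions, so gene values are given relative to it. The median log2 ratio in the regions named 3′ was −0.04 for 2h over 0h, 0.41 for 8h over 0h, 0.46 for 8h over 2h, 0.15 for MEK inhibitor over 8h and 0.52 for MEK inhibitor over 0h. In regions named 5′, these medians were −0.15, 0.18, 0.36, 0.26 and 0.41. A relative log2 ratio is a gene's log2 ratio minus this median. Adding the median back gives the ratio of the deposited signals. Genes are called higher or lower here when the relative log2 ratio is at least 1 in size, which is a size limit and not a test.

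The names of the regions need care. Each region has the length of a flank of 2 kb plus 20% of the gene, if the gene is the stretch between the outer flanks of its 2 regions. This held for 3708 of the 3708 genes by the regions' own coordinates, without use of gene positions from elsewhere. For 18 of 18 genes whose strand is known (9 on each strand), the region named 5′ covered the end of the gene where transcription stops. Nanog, transcribed towards higher coordinates on chromosome 6 (mm10), has its region named 3′ at 122705490 to 122708918 and its region named 5′ at 122713205 to 122716633. Klf4, transcribed towards lower coordinates on chromosome 4, has its region named 3′ at 55531402 to 55534466 and its region named 5′ at 55525144 to 55528208. The deposited names are kept below, and no statement rests on a region being a promoter.

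**Figure D1:**
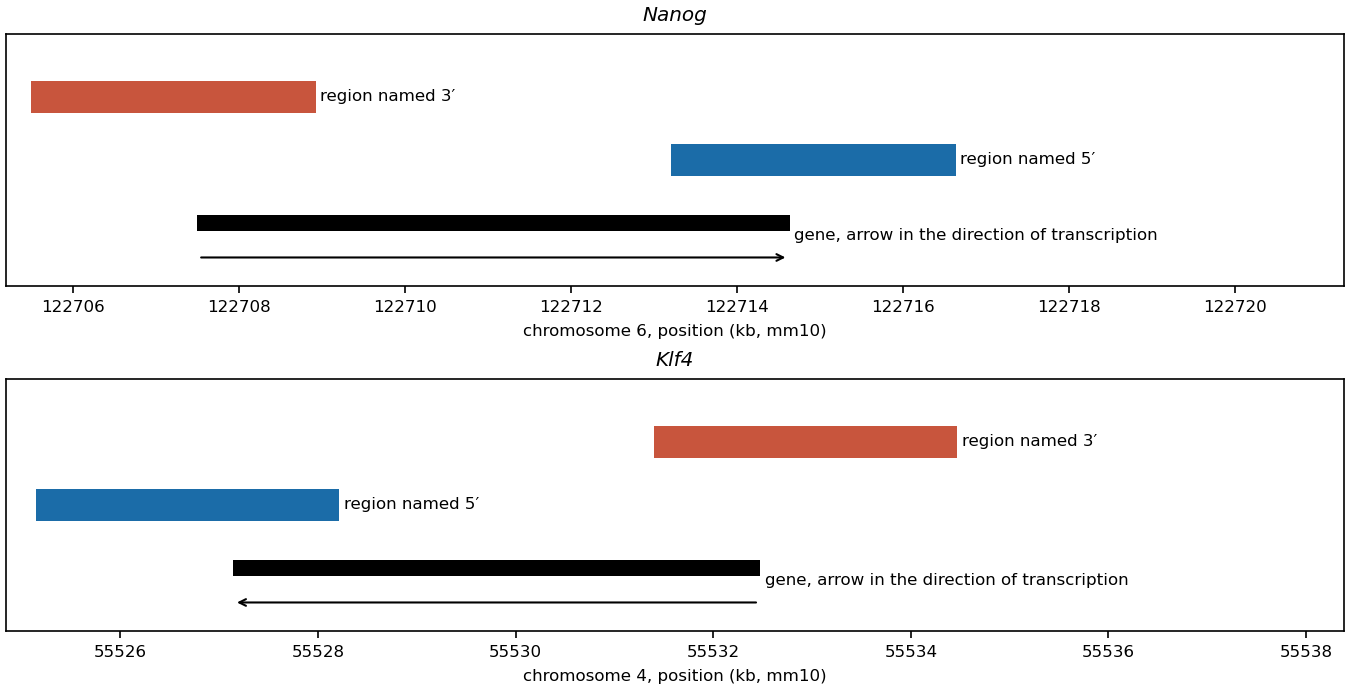
Positions (kb, mm10) of the regions named 5′ (blue) and named 3′ (red) of Nanog and Klf4, with the gene (black bar) and an arrow in its direction of transcription. In both genes the region named 5′ lies at the downstream end, at 122713205 to 122716633 for Nanog and at 55525144 to 55528208 for Klf4.

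The comparison of 2h with 0h asks which genes carried more or less RNAPII early after ERK activation. By list medians, genes for feedback regulators and targets of ERK had more RNAPII at 2h, and genes of naive pluripotency had less, though members went both ways. Among regions named 5′ with mean signal above the median, the highest relative log2 ratios were 3.81 [3.48, 4.15] at Phlda1, a gene induced by growth factor signalling, and 3.48 [3.31, 3.66] at Spry4, a Sprouty inhibitor of receptor tyrosine kinase signalling. The Spry4 signal (chromosome 18, 38584269 to 38589268) was 44.2 (39.3 to 49.5) at 0h and 445 (431 to 459) at 2h, with an Input of 33.3. The lowest there were −2.68 [−2.94, −2.43] at Lefty1 and −2.12 at Lefty2, which encode Nodal antagonists, and −1.74 at Gpx4, a glutathione peroxidase gene. Next came Nanog, a core factor of naive pluripotency, at −1.52 [−1.66, −1.38]. The Nanog signal was 212 (201 to 224) at 0h and 66.8 (61.6 to 72.4) at 2h, with an Input of 28.0.

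Of 18 measured members of the ERK feedback and ETS target list, 9 were higher and 0 lower in the regions named 5′, with a median of 0.99. Besides Phlda1 and Spry4, these included Plaur, the urokinase receptor (2.20), Hbegf, an EGF receptor ligand (1.87), and the ERK phosphatase gene Dusp6 (1.03). That median lay above those of all 10000 random lists matched on signal, a description of these libraries rather than a test. Over regions named 3′, the list median was 0.27 (percentile 99.99), with 4 of 18 higher, among them Plaur (1.94), Spry4 (1.87) and Hbegf (1.44). There 16 members lay above 0 and 2 below. The 2 members with the highest mean signal there went both ways, with Spred2 at 0.25 and Epha4 at −0.42 [−0.52, −0.32]. The ERK immediate response list had a median of 0.32 (percentile 99.99) named 5′ and 0.15 (percentile 98.9) named 3′. Over regions named 5′, it held 4 of 21 members above the limit, namely Myc (1.42), Egr3 (1.27), Egr1 (1.19 [1.11, 1.28]) and Fosl1 (1.08), all genes of transcription factors. Fos, the classic immediate early gene, stood at 0.22 named 5′ and −0.24 named 3′. Named 3′, 13 of the 21 immediate response genes lay above 0 and 8 below. The 2 with the highest mean signal there, Mcl1 and Ier2, stood at −0.05 and −0.04.

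Naive pluripotency genes had a median of −0.57 named 5′ and −0.54 named 3′, below all random lists at both ends. Of the 17 with a ratio named 3′, 12 lay below 0 and 5 above. The 2 with the highest mean signal there were Jam2 (−0.83) and Tet2 (0.29). In regions named 5′, 4 of 18 were lower, namely Nanog, Fbxo15 (−1.07), Prdm14 (−1.03) and Tfcp2l1 (−1.03), and 1 was higher. That gene was Klf5 (1.24), named only after its value was seen. Klf4, a factor of the same network, stood at −0.77 [−0.90, −0.64] named 5′ and −0.89 named 3′. The general pluripotency list had medians of −0.04 (percentile 38.0) and −0.16 (percentile 2.90; 1.02 to 2.24 under some alternatives) in the regions named 5′ and 3′. Its members went both ways, with Pou5f1, which encodes OCT4, at 0.58 and Fgf4, an FGF ligand, at −1.23 named 5′. Among the 7 measured primitive endoderm genes, Sparc stood at 1.19, Nid2 at 0.63 and Sox17 at 0.29 named 5′, and the list median was 0.29 (percentile 96.9). Over regions named 3′ Sparc stood at 0.33 and the list median was 0.02 (percentile 55.03), −0.02 in the deposited signals. In the formative and primed epiblast list the median was 0.16 (percentile 94.0; 0.01 in the deposited signals) named 5′ while the mean was −0.37, since Lefty1, Lefty2 and Igfbp2 (−1.24) lay far below the rest. Named 3′ the median of that list was −0.02 (percentile 40.2). Otx2, a regulator of the formative state, stood at 0.01 named 5′ and 0.06 named 3′.

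Several other lists differed by end at 2h. Housekeeping genes had a median of −0.22 (percentile 0.370) named 5′ and −0.00 (percentile 43.1) named 3′. Replication histone genes had a median of −0.36 (below all random lists) named 3′, with 9 of 9 below 0, and −0.06 (percentile 29.1) named 5′. Genes of other germ layers and trophoblast had medians of 0.25 (percentile 97.6) and −0.03 (percentile 42.04) named 5′ and 3′. MYC and ribosome biogenesis genes had 0.17 (percentile 95.7) and 0.13 (percentile 94.9), and WNT targets 0.12 (percentile 83.4; −0.03 in the deposited signals) and 0.12 (percentile 83.7). Of the fibroblast list only Twist1 was measured, at 1.16 named 5′ and −0.12 named 3′. Under some alternatives the percentiles of immediate response named 3′ (64.3 to 97.19), housekeeping named 5′ (3.78) and other germ layers named 5′ (93.3 to 97.49) came inside the middle 95%.

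Over all genes, 64 were higher and 27 lower in the regions named 5′ at 2h, and 22 higher and 15 lower in the regions named 3′, but 41 and 50, and 20 and 20, by the deposited ratios. At both ends 14 were higher and 7 lower, and 0 were higher at one end and lower at the other. Other genes with high ratios were Trh, which encodes thyrotropin-releasing hormone (2.86 named 5′), Arc, an immediate early gene of neurons (2.41 named 5′), and Pla2g7, a phospholipase A2 gene (2.60 named 3′). In the regions named 3′, 15 genes were listed at 0 at 2h, 14 of them in a stretch of 3.35 Mb on chromosome 1 from 133609008 to 136962448, and these have no 2h ratio there.

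**Figure D2:**
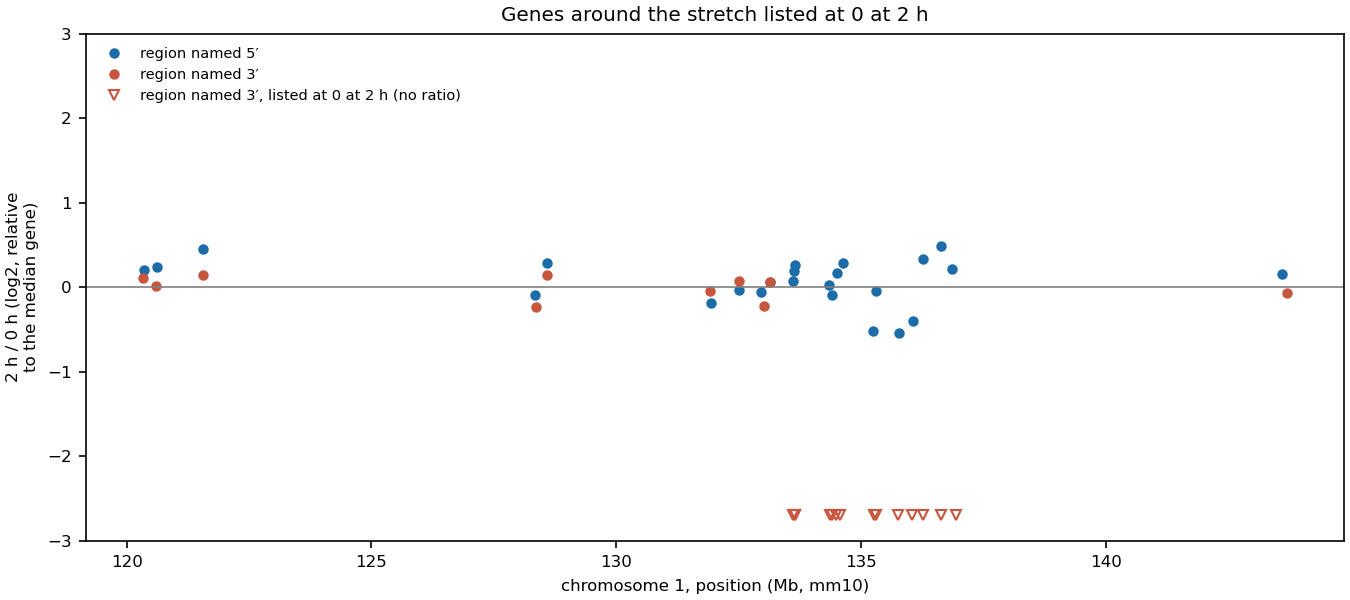
Relative log2 ratio of 2h over 0h (vertical axis) by position on chromosome 1 (Mb, mm10), one point per region, blue for regions named 5′ and red for regions named 3′. Open triangles mark the 14 regions named 3′ listed at 0 at 2h, drawn at a fixed height because they have no ratio; the regions named 5′ of these genes lie between −0.54 and 0.49.

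The comparison of 8h with 0h asks what RNAPII looked like after longer ERK activation. By list medians, ERK feedback genes again had more RNAPII and naive pluripotency genes less. Over regions named 5′, Phlda1 stood at 4.14 [3.81, 4.48], Spry4 at 3.80 [3.63, 3.97], Plaur at 2.84 and Dusp6 at 1.86, and the Spry4 signal was 698 (680 to 715). Nanog stood at −2.35 [−2.52, −2.19] with a signal of 47.2 (42.7 to 52.1), Klf4 at −1.76, Tbx3, another naive pluripotency factor, at −1.82, and Lefty1 at −2.67. Klf4 signal was 176 (166 to 186) at 0h and 59.2 (54.1 to 64.6) at 8h.

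Of the ERK feedback and ETS target list, 11 of 18 members were higher and 1 lower in the regions named 5′, with a median of 1.36 above all random lists. The lower member was Ccnd1, the cyclin D1 gene (−1.35), named after its value was seen. In regions named 3′, the median was 0.69, again above all random lists, with 8 of 18 higher, among them Spry4 (2.54), Plaur (2.37), Phlda1 (1.67) and the phosphatase gene Dusp5 (1.46). The immediate response list had medians of 0.28 (percentile 98.97) named 5′ and 0.27 (percentile 98.5) named 3′, but with Input subtracted both lay inside the middle 95% (92.3 and 85.3). The former did so too among genes above the median signal (92.4). Egr3 (2.78), Fosl1 (1.41), Klf6 (1.32) and Egr1 (1.14) were higher named 5′, while Fos stood at 0.22 and Myc at 0.99.

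Naive pluripotency genes had medians of −0.84 (below all random lists) named 5′ and −0.56 (percentile 0.01) named 3′, and 9 and 7 of the 18 members were lower. These medians were further from 0 than at 2h only relative to the median gene, as the deposited signals gave −0.66 and −0.15 at 8h against −0.72 and −0.58 at 2h. At both ends these included Nanog (−2.35 and −1.92), Tbx3 (−1.82 and −1.79) and Spp1, which encodes osteopontin (−2.13 and −1.76). In regions named 5′, Klf5 (1.16) was again the 1 higher member. The general pluripotency medians were −0.05 (percentile 26.2) and −0.19 (percentile 15.7) named 5′ and 3′, but 0.13 and 0.22 in the deposited signals. Among genes above the median signal the percentile was 0.17 named 5′ (10 members), and named 3′ (6 members) the list lay below all random lists. Fgf4 (−2.31) and Dppa5a (−1.59) were lower named 5′, and Pou5f1 stood at 0.56 named 5′ and 0.66 named 3′. No primitive endoderm gene passed the limit. Sox17, an endoderm transcription factor, stood at 0.73 and 0.69 and Nid2, a basement membrane gene, at 0.78 and 0.35 named 5′ and 3′, and the list medians were 0.25 (percentile 88.0) and 0.16 (percentile 79.3).

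Formative and primed genes split at 8h. Over regions named 5′, Grhl2, an epithelial transcription factor (1.30), Dnmt3b, a de novo DNA methyltransferase (1.16), and Sox11 (1.11, named after its value was seen) were higher. Lefty1 (−2.67), Lefty2 (−2.03) and Igfbp2 (−1.47, named after its value was seen) were lower there, and Otx2 stood at 0.32. The list median of 0.21 (percentile 88.6) therefore has the opposite sign to its mean of −0.13, and in the regions named 3′ the pair was 0.25 (percentile 95.6) and −0.17. MYC and ribosome biogenesis genes had medians of 0.40 (percentile 99) named 5′ and 0.34 (percentile 99.2) named 3′, with 14 of 16 above 0 at each end and none past the limit. The latter percentile was 93.5 with Input subtracted. Members include Odc1 (0.88 named 5′) and Ddx21 (0.79 named 3′). Replication histones had medians of −0.09 (percentile 32.0) named 5′ and −0.41 (percentile 0.99) named 3′, but 0.10 and 0.00 in the deposited signals. WNT targets had medians of 0.28 (percentile 86.4) and 0.28 (percentile 86.3) named 5′ and 3′. Genes of other germ layers had 0.05 (percentile 69.9) and −0.16 (percentile 26.7), the latter 0.25 in the deposited signals. Housekeeping genes had −0.14 (percentile 6.93) and −0.03 (percentile 23.1), but 0.04 and 0.38 in the deposited signals.

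At 8h, 133 genes were higher and 155 lower in the regions named 5′, and 71 higher and 120 lower in the regions named 3′, with 52 higher and 52 lower at both ends. Id1, a target of BMP signalling (2.65), Arc (2.57) and Dusp5 (2.57) were high named 5′. Pla2g7 (2.68), the sulphate transporter gene Slc26a2 (2.21) and Bmp4, a BMP ligand gene (2.06), were high named 3′. Usp48, a deubiquitinase gene (−2.08), and Kit, a receptor tyrosine kinase gene (−1.88), were low named 3′. Before centring on the median gene, the deposited ratios gave 224 genes higher and 85 lower named 5′ and 260 higher and 24 lower named 3′, so the balance of directions depends on the centring.

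Most genes past the limit at 2h were past it at 8h. In the regions named 5′ this held for 45 of 64 higher and 22 of 27 lower genes, and in the regions named 3′ for 16 of 22 and 10 of 15. Independent lists of these sizes would share 2.30, 1.13, 0.423 and 0.487 genes. Simulated counts without any difference, sharing the 0h column, gave far fewer genes past the limit at 2h, on average 0.960, 1.03, 0.650 and 0.440. Of these, 0.560, 0.410, 0.380 and 0.0900 were shared. The draws hold counting error only, not differences between clones or PCR copies, so they do not show what unchanged groups would give. Both comparisons use the 0h column, and a shared control raises the shared part by itself, so the overlap does not measure how lasting the differences were. Spry4, Phlda1, Plaur, Hbegf, Nanog, Lefty1 and Lefty2 are among the shared genes in the regions named 5′.

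**Figure D3:**
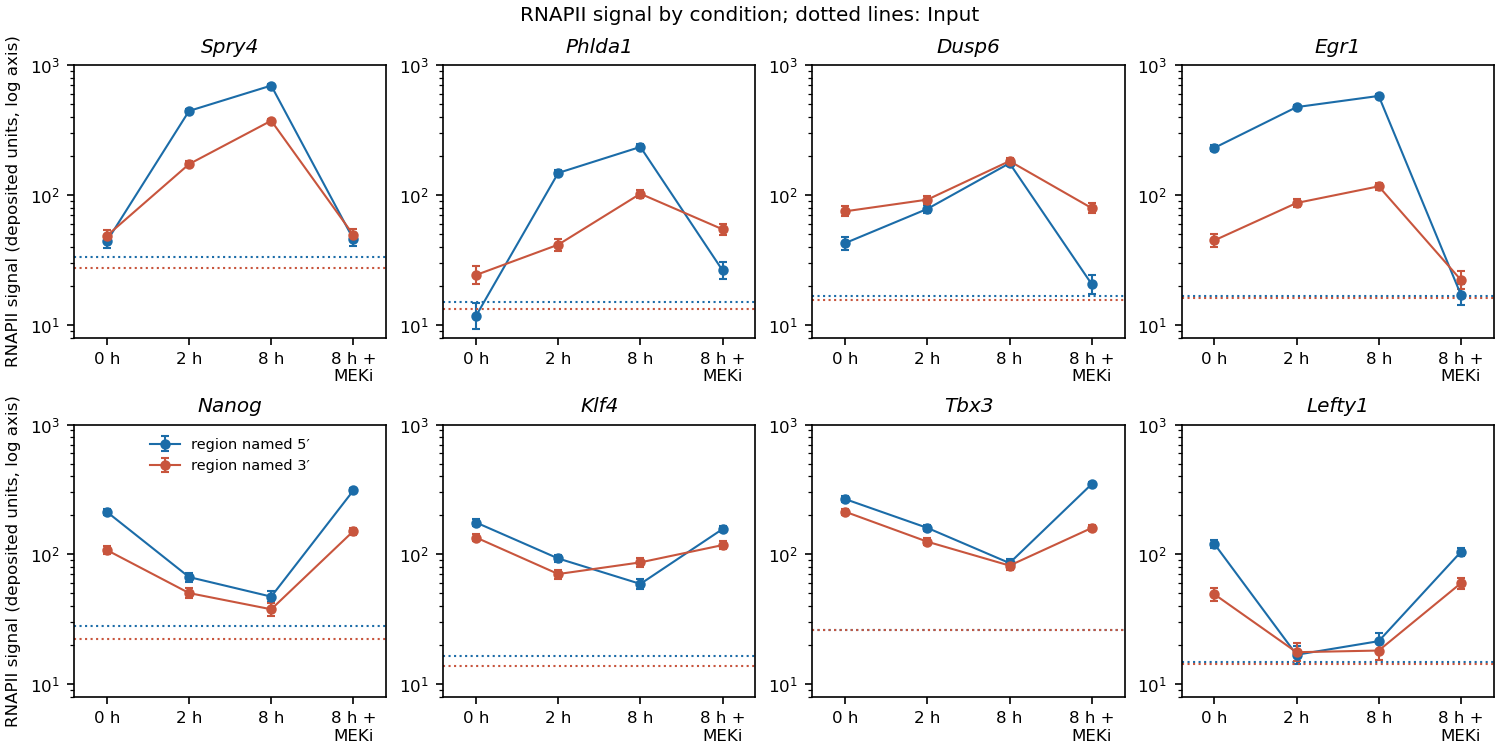
Deposited RNAPII signal (vertical log axis) of 8 genes at 0h, 2h, 8h and 8h with MEK inhibitor (MEKi), blue for the region named 5′ and red for the region named 3′. Points are pooled values, bars are 95% counting intervals and dotted lines are Input; Spry4 named 5′ goes from 44.2 to 698 and back to 45.8, and Nanog from 212 to 47.2 and back to 311.

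The comparison of 8h with 2h asks how RNAPII differed between early and later ERK activation. Feedback genes stood slightly higher at 8h. Naive pluripotency genes stood slightly lower only relative to the median gene, and not in the deposited signals. Against random lists, their relative median stood out in the regions named 5′ (percentile 0.27) but not in those named 3′ (percentile 4.3). In regions named 5′, Egr3 (1.49 [1.31, 1.67]), Spry2, a Sprouty gene (1.21), and Id1 (1.30) were higher at 8h, and Dusp6 stood at 0.81. Tbx3 (−1.25), Klf4 (−1.01 [−1.17, −0.85]) and Fgf4 (−1.10) were lower, and Nanog stood at −0.86 [−1.04, −0.67]. Trh, high at 2h, was lower by a relative log2 ratio of −2.06 [−2.21, −1.91], with signals of 190 (181 to 199) at 2h and 58.2 (53.2 to 63.6) at 8h. Egr1 was at −0.07 and Spry4 at 0.29 [0.24, 0.35].

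The ERK feedback list had medians of 0.30 (percentile 99.7) named 5′ and 0.22 (percentile 98.1) named 3′, with only Spry2 past the limit at each end. The latter percentile was 96.1 among genes above the median signal. Naive pluripotency genes had medians of −0.30 (percentile 0.270) named 5′ and −0.16 (percentile 4.30) named 3′, but 0.05 and 0.30 in the deposited signals, so they were lower only relative to the median gene. MYC and ribosome biogenesis genes had medians of 0.17 (percentile 89.5) and 0.28 (percentile 99.5; 86.4 with Input subtracted), and immediate response genes 0.02 (percentile 57.6) and 0.16 (percentile 93.7), named 5′ and 3′. General pluripotency genes had −0.04 (percentile 28.0) and −0.17 (percentile 13.5), but 0.31 and 0.29 in the deposited signals. The former percentile was 0.44 among genes above the median signal (10 members). Genes of other germ layers had −0.17 (percentile 28.7) and −0.14 (percentile 24.9), but 0.19 and 0.32 in the deposited signals. Histones had −0.08 (percentile 33.1) and −0.00 (percentile 34.1), but 0.28 and 0.46 in the deposited signals. Formative genes had 0.03 (percentile 54.3) and 0.18 (percentile 94.2), and WNT targets 0.05 (percentile 55.2) and 0.22 (percentile 84.3). Primitive endoderm genes had 0.08 (percentile 69.9, mean −0.06) and 0.15 (percentile 86.5), with Sparc at −1.13 named 5′, and housekeeping genes 0.05 (percentile 60.2) and 0.01 (percentile 33.4, mean −0.04). In all, 36 genes were higher and 63 lower named 5′, and 12 higher and 48 lower named 3′, but 146 and 7, and 140 and 5, by the deposited ratios. Over regions named 3′, these included Mroh6 (1.79), Rhoc, a Rho GTPase gene (1.28), and Bmp4 (1.17) among the higher and Ticrr, a replication initiation gene (−1.52), Actn4, an actinin gene (−1.24), and Zfp42, which encodes REX1 (−1.17), among the lower.

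The comparison of MEK inhibitor with 8h asks how RNAPII differed once MEK was inhibited. By the labels the 2 h of inhibitor came after the 8 h of 4OHT, and no column has the same total time without it. The inhibitor and the added time can therefore not be told apart. With MEK inhibitor, RNAPII over ERK target genes was far lower than at 8h, and RNAPII over Nanog, Klf2 and some other naive pluripotency genes was higher. Over regions named 5′, Egr1 stood at −5.34 [−5.62, −5.07], with signals of 580 (564 to 597) at 8h and 17.1 (14.1 to 20.5) with the inhibitor, close to its Input of 16.6. Spry4 stood at −4.19 [−4.35, −4.02], Phlda1 at −3.41, Dusp6 at −3.35, Fos at −2.38 and Myc at −2.01. Nanog stood at 2.46 [2.31, 2.62] with a signal of 311 (297 to 324), and Klf2, a naive pluripotency factor, at 2.46 with signals of 51.7 (47.0 to 56.7) and 340 (326 to 354). Fgf4 (2.30) and Lefty1 (2.03) were higher as well.

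The ERK feedback list had medians of −1.59 named 5′ and −1.05 named 3′, below all random lists, with 12 and 10 of 18 lower. Ccnd1 (1.29, named after its value was seen) was the 1 higher member, named 5′. The immediate response list had medians of −0.67 and −0.51, again below all random lists, with 8 and 2 of 21 lower. Naive pluripotency genes had medians of 0.38 (percentile 99.9) and 0.26 (percentile 98.3), with 10 and 11 of 18 above 0 and 8 and 7 below 0. Past the limit, 6 and 4 were higher and 1 was lower at each end. The lower members, named after their values were seen, were Nr5a2 named 5′ (−1.14) and Klf5 named 3′ (−1.11). MYC and ribosome biogenesis genes had medians of −0.56 (percentile 0.160) and −0.43 (percentile 0.320), with Ddx21 at −0.87 and −0.94. Replication histones had medians of 0.45 (percentile 96.9) and 0.54 (percentile 99.7), with H2afx, a variant histone gene, at 1.49 named 5′. Genes of other germ layers had 0.41 (percentile 90.4) and 0.56 (percentile 99.2), with Cdx2, a trophoblast and gut factor, at 1.07 named 3′. Formative genes had 0.19 (percentile 84.6) and 0.41 (percentile 98.4), and housekeeping genes 0.17 (percentile 97.46) and 0.21 (percentile 94.1). General pluripotency genes went both ways, with Dppa5a (1.76) and Fgf4 higher and Dppa4 (−1.42) and Utf1 (−1.35) lower named 5′. Their medians were 0.05 (percentile 78.4) and −0.13 (percentile 20.3; mean 0.08 and, in the deposited signals, median 0.02), and Pou5f1 stood at −0.48 and −0.69. Primitive endoderm genes had −0.00 (percentile 55.1; 0.25 in the deposited signals) and −0.16 (percentile 24.0), with Nid2 at −1.23 and −0.71 and Sox17 at −0.13 and 0.01. WNT targets had −0.01 (percentile 36.5; 0.25 in the deposited signals) and 0.00 (percentile 48.1). Under some alternatives the percentiles of immediate response named 5′ (2.71), naive pluripotency named 5′ (89.9), formative named 3′ (69.6 to 90.7) and other germ layers named 3′ (89.7 to 97.13) came inside the middle 95%.

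In all, 210 genes were higher and 180 lower named 5′, and 101 higher and 91 lower named 3′, but 434 and 112, and 209 and 72, by the deposited ratios. At both ends, relative to the median gene, 50 were higher and 64 lower. Ppm1j, a phosphatase gene (−3.49), and Nrp2, a semaphorin receptor gene (−2.81), were low named 5′. Rhoc (−2.81), the inositol kinase gene Itpk1 (−2.39) and Bmp4 (−2.27) were low named 3′. Of the genes higher at 8h, 102 of 133 (76.7%) named 5′ and 56 of 71 (78.9%) named 3′ were lower by at least 1 with the inhibitor. Of the genes lower at 8h, 94 of 155 (60.6%) and 41 of 120 (34.2%) were higher by at least 1. The contrast between directions named 3′ is not stable, since with Input subtracted 52.0% of the higher and 64.5% of the lower genes moved back there, and at a limit of 0.5 66.5% of the lower. Across genes the relative log2 ratios of 8h over 0h and of inhibitor over 8h had Pearson r of −0.82 and −0.79. Simulated counts without any difference, with counting error only, gave −0.44 at both ends, since both ratios hold the 8h column.

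The ratio of 2h over 0h shares no column with that of inhibitor over 8h. The pair had r of −0.61 named 5′ and −0.53 named 3′, against 0.00 in simulated counts, which hold counting error only. Genes are not independent replicates, so these r describe the tables. Genes chosen at one end were also measured at the other. At the other end, 56 of the 133 genes higher named 5′ and 52 of the 71 higher named 3′ were lower by at least 1 with the inhibitor. Of the genes lower at 8h, 35 of the 155 named 5′ and 37 of the 120 named 3′ were higher by at least 1 at the other end. The 71 genes higher at 8h named 3′ had a median of 1.38 at 8h and −0.03 with the inhibitor, both over 0h, in their regions named 5′. The 133 higher named 5′ had 0.83 and −0.07 in their regions named 3′. For the 155 lower named 5′ these medians were −0.88 and −0.04, and for the 120 lower named 3′ they were −0.89 and −0.18. The MEK inhibitor column pools fewer clones than the others by the labels, and clone a is missing from it.

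**Figure D4:**
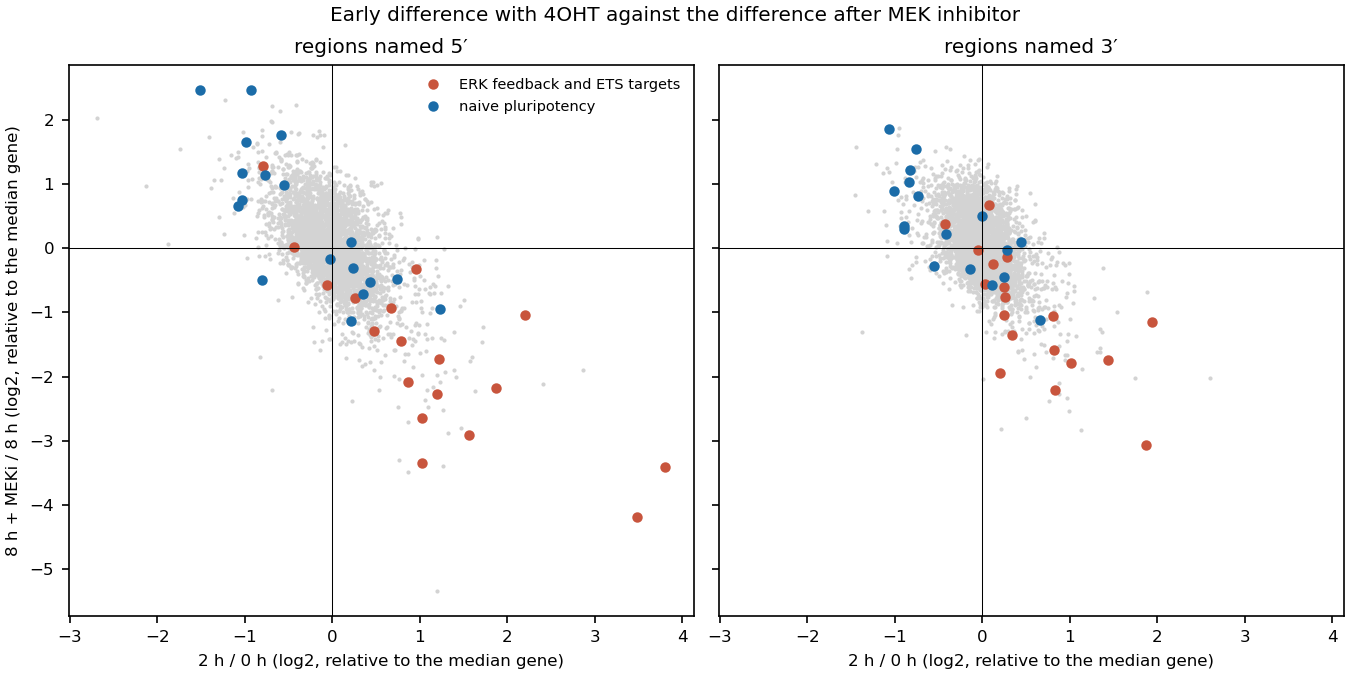
Relative log2 ratio of 2h over 0h (horizontal axis) against that of MEK inhibitor over 8h (vertical axis), grey points for all genes, red for ERK feedback and ETS targets and blue for naive pluripotency genes. The left panel shows regions named 5′ (r of −0.61 across genes) and the right panel regions named 3′ (r of −0.53).

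The comparison of MEK inhibitor with 0h asks what remained different after the inhibitor. No measured naive pluripotency gene was past the limit at either end, and 2 of 18 ERK feedback genes were past it named 5′, Plaur above and Dusp6 below. In regions named 5′, Egr1 was far below 0h at −4.16 [−4.45, −3.89], and Fos (−2.13), Dusp6 (−1.46) and Cyr61, an immediate early matricellular gene (−1.29), were lower too. Spry4 stood at −0.36 [−0.59, −0.12], Nanog at 0.14 [0.04, 0.24], and, both named after their values were seen, Tbx3 at −0.02 and Fgf4 at 0.02. Id1 (2.09 [1.87, 2.32]) and Plaur (1.83) remained higher than at 0h, with an Id1 signal of 28.6 (24.7 to 32.9) at 0h and 161 (152 to 171) with the inhibitor.

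ERK feedback genes had medians of −0.28 (percentile 0.06) named 5′ and −0.26 (percentile 0.03) named 3′, but 0.12 and 0.26 in the deposited signals. Naive pluripotency genes had −0.31 (below all random lists) and −0.35 (percentile 0.01), but 0.10 and 0.17 in the deposited signals. Both lists were therefore lower only relative to the median gene. Genes of other germ layers and trophoblast had medians of 0.62 and 0.54 (both percentile 99.99), with 8 of 8 above 0 at each end. They included Gsc, an organizer gene (0.83 and 0.74), Sox1, a neural gene (0.74 and 0.62), and Msx1 (0.80 named 5′). Formative genes had medians of 0.25 (percentile 97.9) and 0.34 (percentile 99.8). The mean of that list named 5′ was −0.01, and Otx2 differed by end at −0.63 named 5′ and 0.81 named 3′. Among primitive endoderm genes Foxa2 was higher named 3′ (1.05) and Sox17 stood at 0.63 and 0.73, with list medians of 0.12 (percentile 83.2) and −0.11 (percentile 21.2; mean 0.07 and, in the deposited signals, median 0.42). General pluripotency genes had 0.06 (percentile 82.3, mean −0.09) and −0.17 (percentile 3.35; 0.35 in the deposited signals). Immediate response genes had −0.12 (percentile 5.12) and −0.08 (percentile 7.39), but 0.29 and 0.44 in the deposited signals. MYC genes had −0.08 (percentile 32.8) and −0.08 (percentile 14.1), but 0.33 and 0.44 in the deposited signals. Histones had 0.29 (percentile 98.1) and 0.21 (percentile 95.6), and WNT targets 0.11 (percentile 57.8) and 0.39 (percentile 96.6). Housekeeping genes had −0.01 (percentile 71.4; 0.40 in the deposited signals; mean 0.03) and 0.20 (percentile 97.6). Under some alternatives the percentiles of naive pluripotency named 5′ (4.03), formative named 5′ (70.6 to 97.35), histones named 5′ (91.7 to 97.39) and housekeeping named 3′ (47.45 to 97.46) came inside the middle 95%.

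In all, 32 genes were higher and 18 lower named 5′, and 10 higher and 24 lower named 3′, with 5 higher and 6 lower at both ends. Kat6b, a histone acetyltransferase gene, was lower at both ends (−1.18 and −1.29), as were Igfbp2 (−1.22 and −1.27) and Arih2, a ubiquitin ligase gene (−1.06 and −1.48). The deposited ratios gave 251 genes higher and 5 lower named 5′ and 312 higher and 4 lower named 3′, because the median gene itself was higher. Over the 5 comparisons, 43 of 110 list percentiles lay outside the middle 95%, where chance alone would give 5.50 for independent lists.

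**Figure D5:**
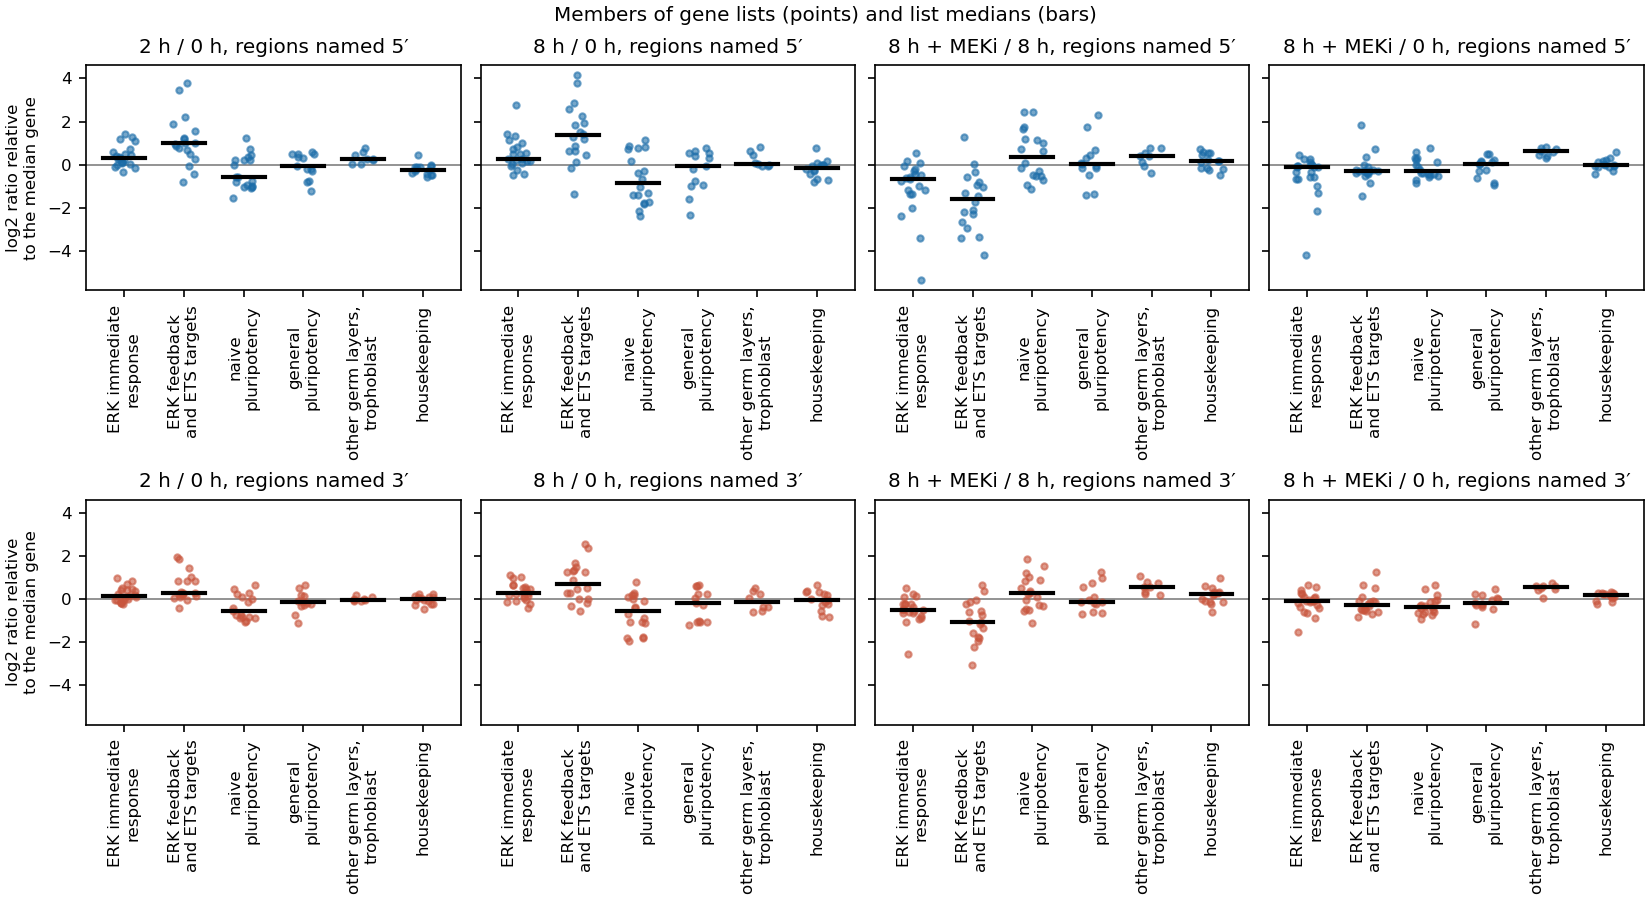
Relative log2 ratios (vertical axis) of the members of 6 gene lists (points) with each list's median (black bar), for regions named 5′ (blue, upper panels) and named 3′ (red, lower panels). Each panel is 1 comparison; the ERK feedback median named 5′ is 0.99 at 2h, 1.36 at 8h and −1.59 for MEK inhibitor over 8h.

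Comparing the ends asks whether RNAPII differed alike along a gene. For the 18 genes of known strand, Spry4 among them, the region named 5′ is the end where transcription stops. ERK feedback genes differed more in the regions named 5′ than in those named 3′ for 2h and 8h over 0h and inhibitor over 8h. Their median difference of relative log2 ratios (named 5′ minus named 3′) was 0.56 for 2h over 0h and 0.60 for 8h over 0h. Both lay above all random lists. For inhibitor over 8h it was −0.48, below all, for 8h over 2h 0.15 (percentile 97.79) and for inhibitor over 0h 0.02 (percentile 71.95). At 8h, 16 of 18 members had the larger ratio named 5′, for instance Phlda1 (4.14 against 1.67) and Spry4 (3.80 against 2.54). Immediate response genes had median differences of 0.16 (percentile 97.7) at 2h, 0.10 (percentile 79.3) for 8h over 0h, −0.08 (percentile 7.66) for 8h over 2h and −0.43 (below all random lists) for the inhibitor over 8h. For inhibitor over 0h it was −0.21 (percentile 0.190), and for inhibitor over 8h Egr1 stood at −5.34 against −2.54. With Input subtracted the 2h and inhibitor over 8h percentiles were 94.7 and 3.50, inside the middle 95%. Naive pluripotency genes had median differences of −0.02 (percentile 34.2) at 2h and 0.04 (percentile 51.8) at 8h. Other lists lay outside the middle 95% too. For 2h over 0h these were housekeeping (−0.18, percentile 0.46), histones (0.29, percentile 99.6), primitive endoderm (0.33, percentile 98.71) and other germ layers (0.31, percentile 98.74). Other germ layers did so for 8h over 0h (0.32, percentile 97.63). Formative genes did so for 8h over 2h (0.24, percentile 99.07) and inhibitor over 0h (−0.23, percentile 0.52). Of the 81 genes whose mean over both ends was higher at 8h, 67 had the larger ratio named 5′, and of the 102 that were lower, 68 were further below 0 named 5′. Over all genes the log2 ratios of 8h over 0h had the wider spread named 5′ (standard deviation 0.59 against 0.51). That by itself favours such counts, and no value without a difference was set beside them. The random lists were matched on mean signal and not on the size of the ratio. Genes whose mean over both ends was higher had median differences of 0.34 for 2h over 0h and 0.37 for 8h over 0h. Those lower for inhibitor over 8h had −0.38. The percentiles of the ERK lists therefore do not set them apart from other genes with large ratios. Regions of neighbouring genes can overlap, and ChIP-seq reads carry no strand, so a region's signal can include another gene's RNAPII.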

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

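The tests with Input subtracted, with pseudocounts of 1 and 4, without overlapping regions and without the genes at 0 at 2h were chosen after seeing the data. Here 2h/0h, 8h/0h, 8h/2h, MEKi/8h and MEKi/0h stand for the 5 comparisons, MEKi for 8h with MEK inhibitor, and 5′ and 3′ for the regions so named. Gene counts at each end start from the deposited ratios, which gave 91, 309, 153, 546 and 256 genes past the limit (5′) and 40, 284, 145, 281 and 316 (3′) in that order of comparisons. Counts at both ends, counts shared by 2h and 8h, and shares moving back use ratios relative to the median gene, so they are not parts of the counts at each end.

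Of 3161 alternative values of named genes, 2232 stayed within the counting interval and 929 moved. For the 201 values past the limit the sign changed in 0 under pseudocounts of 1 and 4 and quantile normalization, and in 0 of the 168 left with Input subtracted. Adding or subtracting the same value in both columns cannot change which is larger. Only the recentring on the median could then turn a sign, so for pseudocounts and Input this result was nearly fixed beforehand. Of the 442 values below the limit, the sign was another in 46 as deposited, in 11 after quantile normalization and in 4 with a pseudocount of 4, and in 19 of 421 with Input subtracted. Of the list percentiles 734 kept their side of the middle 95%, 34 moved inside, 30 moved outside and 1 crossed to the other side of 50. Of the gene counts 135 stayed within 1.5 times the reported one and 147 did not. The medians of ERK feedback genes at 2h, 8h and with MEK inhibitor over 8h stayed on their side under each alternative run, as did those of naive pluripotency genes at 2h and 8h over 0h.

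With Input subtracted, the genes past the limit named 5′ numbered 437 (2h/0h), 790 (8h/0h), 807 (8h/2h), 927 (MEKi/8h) and 799 (MEKi/0h). The genes past the limit named 3′ numbered 253 (2h/0h), 1180 (8h/0h), 1160 (8h/2h), 761 (MEKi/8h) and 1349 (MEKi/0h). At both ends, relative to the median gene, it was 112 (2h/0h), 308 (8h/0h), 170 (8h/2h), 354 (MEKi/8h) and 61 (MEKi/0h). Percentiles that moved inside the middle 95% were ERK immediate response 97.19 (2h/0h, 3′), 85.3 (8h/0h, 3′) and 92.3 (8h/0h, 5′), MYC 93.5 (8h/0h, 3′) and 86.4 (8h/2h, 3′), formative 90.7 (MEKi/8h, 3′) and 85.1 (MEKi/0h, 5′), housekeeping 3.78 (2h/0h, 5′), naive pluripotency 89.9 (MEKi/8h, 5′), other germ layers 97.05 (2h/0h, 5′) and 97.13 (MEKi/8h, 3′), histones 91.7 (MEKi/0h, 5′). Percentiles that moved outside it were ERK immediate response 0.13 (MEKi/0h, 3′), WNT targets 97.60 (MEKi/0h, 3′), formative 97.71 (8h/0h, 3′), naive pluripotency 1.29 (8h/2h, 3′), primitive endoderm 99.25 (2h/0h, 5′), 98.67 (8h/0h, 5′) and 99.77 (MEKi/0h, 5′), histones 99.09 (MEKi/8h, 5′). Percentiles that fell to the other side of 50 were housekeeping 47.45 (MEKi/0h, 3′). For the difference between ends the percentiles were ERK immediate response 94.7 (2h/0h, inside the middle 95%), ERK immediate response 3.50 (MEKi/8h, inside the middle 95%) and housekeeping 4.76 (2h/0h, inside the middle 95%). Moving back after the inhibitor were 52.0% of genes higher at 8h (3′) and 64.5% of genes lower at 8h (3′). Shared by 2h and 8h, relative to the median gene, were 94 higher (3′), 122 higher (5′), 63 lower (3′) and 80 lower (5′). Subtraction widens every ratio of a region near Input by construction, which raises the counts; for the percentiles and the shares moving back the cause was not tested.

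At a limit of 0.5, the genes past the limit named 5′ numbered 729 (2h/0h), 1353 (8h/0h), 1449 (8h/2h), 1586 (MEKi/8h) and 1478 (MEKi/0h). The genes past the limit named 3′ numbered 337 (2h/0h), 1755 (8h/0h), 1749 (8h/2h), 1266 (MEKi/8h) and 2009 (MEKi/0h). At both ends, relative to the median gene, it was 173 (2h/0h), 656 (8h/0h), 437 (8h/2h), 798 (MEKi/8h) and 206 (MEKi/0h). Moving back after the inhibitor were 66.5% of genes lower at 8h (3′). Shared by 2h and 8h, relative to the median gene, were 111 higher (3′), 186 higher (5′), 112 lower (3′) and 163 lower (5′). A lower limit passes more genes by construction; for the share moving back the cause was not tested.

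Among genes above the median mean signal, the genes past the limit named 5′ numbered 55 (2h/0h), 180 (8h/0h), 85 (8h/2h), 252 (MEKi/8h) and 100 (MEKi/0h). The genes past the limit named 3′ numbered 26 (2h/0h), 182 (8h/0h), 84 (8h/2h), 130 (MEKi/8h) and 136 (MEKi/0h). At both ends, relative to the median gene, it was 66 (8h/0h), 11 (8h/2h) and 66 (MEKi/8h). Percentiles that moved inside the middle 95% were ERK feedback 96.1 (8h/2h, 3′), ERK immediate response 64.3 (2h/0h, 3′), 92.4 (8h/0h, 5′) and 2.71 (MEKi/8h, 5′), formative 69.6 (MEKi/8h, 3′) and 73.0 (MEKi/0h, 5′), housekeeping 97.23 (MEKi/0h, 3′). Percentiles that moved outside it were ERK immediate response 1.03 (MEKi/0h, 3′), general pluripotency 2.24 (2h/0h, 3′), 0 (8h/0h, 3′), 0.17 (8h/0h, 5′) and 0.44 (8h/2h, 5′), primitive endoderm 98.34 (2h/0h, 5′), histones 99.78 (MEKi/8h, 5′). Shared by 2h and 8h, relative to the median gene, were 6 lower (3′). Regions named 5′ above Input were 99.515% (0h), 99.838% (2h), 99.838% (8h) and 99.784% (MEKi). Regions named 3′ above Input were 99.676% (0h), 99.569% (2h), 99.622% (8h) and 100% (MEKi). Fewer genes enter by construction; for the percentiles and the shares above Input the cause was not tested.

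Among genes above the median mean signal at both ends, for the difference between ends the percentiles were ERK immediate response 79.2 (2h/0h, inside the middle 95%) and naive pluripotency 99.98 (MEKi/8h, outside the middle 95%). For these values the cause was not tested.

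Without the lower 25% of mean signal, percentiles that moved inside the middle 95% were ERK immediate response 94.0 (2h/0h, 3′), formative 83.2 (MEKi/8h, 3′) and 70.6 (MEKi/0h, 5′), housekeeping 94.7 (MEKi/0h, 3′), other germ layers 93.3 (2h/0h, 5′) and 89.7 (MEKi/8h, 3′), histones 97.39 (MEKi/0h, 5′). Percentiles that moved outside it were ERK immediate response 0.25 (MEKi/0h, 5′), formative 97.75 (8h/0h, 3′), housekeeping 97.93 (MEKi/8h, 5′), histones 99.09 (MEKi/8h, 5′). Regions named 5′ above Input were 99.497% (0h), 99.748% (2h), 99.712% (8h) and 99.712% (MEKi). Regions named 3′ above Input were 99.712% (0h), 99.533% (2h), 99.712% (8h) and 99.964% (MEKi). For these values the cause was not tested.

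After median-centring, the genes past the limit named 5′ numbered 99 (8h/2h) and 50 (MEKi/0h). The genes past the limit named 3′ numbered 60 (8h/2h) and 34 (MEKi/0h). The median log2 ratios taken away here (0.46, 0.36, 0.52 and 0.41) explain these lower counts by construction.

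Without overlapping regions, percentiles that moved inside the middle 95% were housekeeping 95.7 (MEKi/0h, 3′), other germ layers 97.46 (2h/0h, 5′). Percentiles that moved outside it were primitive endoderm 97.92 (2h/0h, 5′) and 97.99 (MEKi/0h, 5′). For these values the cause was not tested.

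With a pseudocount of 1, percentiles that moved inside the middle 95% were housekeeping 97.46 (MEKi/0h, 3′). For these values the cause was not tested.

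With a pseudocount of 4, the genes past the limit named 5′ numbered 97 (8h/2h). The genes past the limit named 3′ numbered 89 (8h/2h). At both ends, relative to the median gene, it was 14 (8h/2h). Percentiles that moved inside the middle 95% were formative 97.35 (MEKi/0h, 5′), housekeeping 96.4 (MEKi/0h, 3′). Percentiles that moved outside it were ERK immediate response 2.21 (MEKi/0h, 5′), general pluripotency 2.01 (2h/0h, 3′), housekeeping 97.50 (MEKi/8h, 5′). A pseudocount shrinks every ratio by construction, which lowers the counts; for the percentiles the cause was not tested.

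After quantile normalization, the genes past the limit named 5′ numbered 70 (8h/2h), 362 (MEKi/8h) and 43 (MEKi/0h). The genes past the limit named 3′ numbered 153 (8h/0h), 48 (8h/2h), 173 (MEKi/8h) and 34 (MEKi/0h). Percentiles that moved inside the middle 95% were formative 95.2 (MEKi/0h, 5′), naive pluripotency 4.03 (MEKi/0h, 5′). Percentiles that moved outside it were ERK immediate response 1.28 (MEKi/0h, 5′), MYC 97.94 (2h/0h, 3′), general pluripotency 1.02 (2h/0h, 3′), primitive endoderm 99.09 (2h/0h, 5′) and 99.67 (8h/2h, 3′), histones 98.33 (MEKi/0h, 3′). For the counts and the percentiles the cause was not tested.

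Without the genes at 0 at 2h, percentiles that moved inside the middle 95% were other germ layers 97.49 (2h/0h, 5′). For these values the cause was not tested.

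No paired analysis was possible because the columns pool clones. For the same reason the replicate block, leaving out each replicate, the fit of only the 2 groups compared, count-model tests (edgeR and DESeq2 with their size factors), limma with and without trend, camera with preset or estimated correlation and a stricter adjusted p were not run. The pseudocount at 0.5 times a main one had no main one to start from, and each gene has 1 entry, so keeping all entries changes nothing. Depth sets the counting error of a single gene, with a median half-width of the 95% interval of a log2 ratio between 0.18 and 0.22.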

Other observations

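All tests in this part were chosen after the result was seen, except the test of exchanged sheet names, which was set before its result was seen. Square brackets in this part hold 95% bootstrap intervals over genes, not counting intervals.

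After MEK inhibitor the Hox genes, regulators of body axis identity, carried more RNAPII than at 0h relative to the median gene. Their median relative log2 ratio was 0.63 named 5′ (32 of 33 above 0) and 0.60 named 3′ (31 of 33 above 0), above all random lists of the same size at both ends. The direction was the same in the deposited signals (1.04 and 1.12) and after quantile normalization (0.60 and 0.59). Hoxa6 (1.14) and Hoxa7 (1.12) stood highest named 5′. The Hox genes lie in clusters with neighbouring and partly overlapping regions, so these are not 33 independent values. Part of the difference was there before the inhibitor: 8h over 0h gave 0.27 (percentile 99.88) named 5′ and 0.26 (percentile 99.69) named 3′. For the inhibitor over 8h the medians were 0.13 (percentile 68.5, 28 of 33 above 0) named 5′ and 0.24 (percentile 96.7, 33 of 33 above 0) named 3′, both inside the middle 95% of random lists. For 2h over 0h they were 0.13 (percentile 98.4; −0.02 in the deposited signals) named 5′ and −0.14 (percentile 0.570) named 3′. Which step the difference from 0h belongs to is left open, and it was found and tested on the same tables.

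Ribosomal protein genes (Rpl and Rps, 80 genes) carried less RNAPII at 2h in the regions named 5′, with a median relative log2 ratio of −0.24, below all random lists, and 71 of 80 below 0. The value was −0.39 in the deposited signals and −0.25 after quantile normalization. In the regions named 3′ the median was −0.04 (percentile 7.59), and for 8h over 2h named 5′ it was 0.25, with 58 of 80 above 0. The random lists were matched on mean signal only by bins, and the median mean signal of this family named 5′ was 165. Signal is not matched within a bin, so a difference shared by genes of the highest signal is not excluded. No explanation for this family was tested.

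The regions named 5′ lie at the downstream end of all 18 genes of known strand. Exchanged coordinates with values left in place are excluded: for 84 pairs of overlapping regions the values beside the coordinates differed by a median of 0.124 (absolute log2 ratio), against 0.420 for the other sheet's values. Exchanged sheet names stay open and have the values they need, since 49 regulators of development had a 0h to Input log2 ratio higher by a median of 0.85 in the regions named 3′, above all random lists (36 of 49 above 0). Their medians were 1.81 named 3′ and 0.85 named 5′, while the median difference over all genes was −0.21. The design gives no biological explanation, and none was tested.

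In the regions named 3′, 15 genes are listed at 0 at 2h, and 14 of the 14 genes within a stretch of 3.35 Mb on chromosome 1 are among them. Loss of RNAPII over the whole of these genes at 2h is excluded as the cause, as their regions named 5′ had a median relative log2 ratio of 0.079 [−0.089, 0.21]. Those regions cannot exclude a loss at the other end alone, but the listed 0 argues against it for these 15 genes. Loss of RNAPII would leave background reads. Of the 3708 regions named 3′, 0 are at 0 at 0h, 8h or with MEK inhibitor, and 2 are in Input, whose median there was 18.74. At the 0h signal the 15 regions named 3′ would hold from 96 to 2688 reads each at 2h, where 0 are listed. A stretch missing from the counted 2h reads of that table is a candidate explanation for these 14 genes, and the other region of all 15 has a 2h value. It says nothing on Rnd3 on chromosome 2, where the signal named 3′ was 61.15 at 0h, 0 at 2h and 70.2 at 8h.

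Signal over most genes was higher at 8h and with MEK inhibitor than at 0h. A single scaling factor for the 8h column is excluded as the whole cause, because the median log2 ratio differed between ends by 0.22 [0.20, 0.25], beyond the bound of 0.1. Among 10 bins by enrichment, the highest and lowest differed beyond that bound by 2 of 3 definitions, both built from columns under comparison, and not by the definition from 2h over Input (0.19 [0.05, 0.37] named 3′). For the MEK inhibitor column the ends differed by 0.11 [0.10, 0.13], reaching the bound, and again only the 2 definitions built from columns under comparison went beyond it, so a single factor stays open. A higher share of enriched fragments stays open too: the bin of lowest enrichment had medians from 0.28 [0.23, 0.34] to 0.47 over both ends and the 3 definitions, but it stood above Input by 0.20 to 0.36 at 0h, so the bound of 0 written for it was wrong. The definition of the bins was changed once after a first look, and an effect of ERK activation or the inhibitor remains open, untested.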
